A study of Mus musculus with 2 samples.

How the data were processed

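H3K9ac was measured by ChIP-seq in mouse forebrain at embryonic day 14.5, in 2 biological replicates of 1 group, per the labels. Embryos of the C57BL/6N background were pooled, 24 for replicate 1 and 34 for replicate 2, and the fragment size range was 300 to 500 bp, per the labels. The authors deposited 4 peak lists in the narrowPeak format on mm10. They called peaks on each replicate alone and on both replicates together, and the replicated list was derived from the pooled and single-replicate lists, per the text files deposited with the samples. Those text files name 2 further parent files, of a kind not stated, for the list of replicate 1 and 1 for that of replicate 2. The peak caller and its version are not given in the sources used here.

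The signal value of each peak, as deposited by the authors, was read as a ratio, the fold enrichment over background. The sources do not name the quantity, and this reading rests on the file format, on the values and on the fold change named for matching tracks. The p and q of each peak, as deposited by the authors, were read from the same format as −log10 values. The lowest −log10 p was just above 2 in every list, which is a permissive threshold, and 29.3% of replicate 1 peaks, 24.8% of replicate 2 peaks and 2.99% of replicated peaks had a q above 0.01. Lists made from different numbers of reads differ in how many weak peaks pass. Peak numbers, shares of distal peaks and overlap are all moved by this. No read numbers are in the lists, so the depth per sample is unknown and no interval that needs it is given. Binomial intervals (95%, exact) cover counting error only.

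Coordinates are 1-based on mm10. Gene positions came from GENCODE release M21 and sequence from GRCm38.p6, the same build. There were 21911 protein-coding genes with distinct symbols on the 21 main chromosomes. Peaks on other contigs were left out of the comparisons. A gene was marked when a peak overlapped the window of 1000 bp on either side of the 5′ end of its gene record, with 1 such end per gene. The highest fold enrichment of a peak in the window was the gene's value. The location of peaks used the 5′ ends of all annotated transcripts of all genes. The CpG ratio is the observed over expected number of CpG dinucleotides in the window.

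The choices that follow were fixed before the data were examined, except where stated. There were 25 gene lists: 6 of forebrain lineages (patterning factors, radial glia, cortical excitatory, GABAergic, diencephalon, pan-neuronal), 1 of midbrain, hindbrain and spinal cord factors, Hox genes, 8 of other cells of the brain or its coverings (oligodendrocyte precursors, myelin, astrocytes, microglia, endothelium, erythroid cells, meninges, choroid plexus), 5 of other tissues (hepatocytes, muscle, epidermis, germline, olfactory receptors) and 4 of genes not tied to a cell type (ribosomal proteins, oxidative phosphorylation, replication-dependent histones, histone acetyltransferases and deacetylases). Nkx2-2 and Otx2 are each in 2 lists. The ribosomal protein, oxidative phosphorylation and replication-dependent histone lists were drawn by symbol and not screened for forms limited to some tissues. The share of marked members was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 25 lists and a threshold of 0.05. These tests compare genes within these libraries, not conditions. They count genes as independent, so p-values may be too small for lists of neighbouring genes, such as Hox, histone and olfactory receptor genes. The comparison matched on the CpG ratio used 5 quintiles, a Mantel-Haenszel odds ratio and an exact conditional test over the strata. The median fold enrichment of a list was placed among 10000 random lists of as many marked genes, where at least 3 members were marked. Overlap of replicates required 50% of the smaller peak and was set beside 100 shuffles. Domains joined peaks at most 1000 bp apart. Distal peaks lay beyond 1000 bp of any TSS and were given to the nearest protein-coding TSS within 100000 bp. The test of lists in domains of at least 5000 bp was chosen after the data were seen, as were the bounds of the top and bottom 2.5% of random lists, the search at other transcripts and the distance to the other replicate's peak. The exact conditional test replaced a Mantel-Haenszel chi-square after a first run, and both gave 1 list above and 6 below other genes.

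The genes named are, for each list, up to 4 marked members with the highest fold enrichment. For the 6 forebrain lists, up to 4 unmarked members in alphabetical order are named. Also named are the genes of the 15 widest domains, the 15 genes with most distal peaks, the 10 strongest genes in the top 5% of both replicates, and the 5 strongest genes marked in each replicate only. Names were left out for length, and names outside the rule are said to be so.

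Alternatives were a −log10 q of at least 5, a fold enrichment of at least 4, equal numbers of top peaks, an overlap of 1 bp or of 50% of both peaks, −log10 p or width in place of fold enrichment, each replicate left out in turn, the pooled peaks, windows of 500 and 2500 bp, all transcript 5′ ends, gaps of 0 and 3000 bp, and shorter distances. The share of 32-base words of a window that occur once in the genome was computed for lists with near-identical copies. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9. They were tested on simulated data. Overlap and joining gave the same counts as bedtools 2.31.1 on 800 simulated intervals. In 40 simulated rounds over 21911 genes, the list test called any list in 1 round without an effect. It called 386 of 400 changed lists in the set direction and 0 in the other. The simulated changes were large and the shortest lists were not among the changed ones. The power for small differences or short lists is therefore unknown.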

Results

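Histone H3 acetylated at lysine 9 (H3K9ac), a mark found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the forebrain of mouse embryos at embryonic day 14.5. The forebrain at this age holds dividing radial glia, newborn neurons of the cortex and of the ventral telencephalon, the diencephalon, and blood vessels and other non-neural cells. There was 1 group with 2 biological replicates. Replicate 1 was a pool of 24 embryos and replicate 2 a pool of 34, and each pool held male and female embryos. The data were 4 peak lists on the mm10 build: the peaks of each replicate, the peaks called on both replicates together (pooled), and the part of the pooled peaks that the authors kept as replicated. On chromosomes 1 to 19, X and Y these held 67904, 44316, 60512 and 35034 peaks. The lists give no read numbers, so the depth of each library is unknown. With 1 group, no condition was compared. The questions were which genes and regions carried the mark in this tissue, and how far the replicates gave the same answer. The authors' signal value for each peak is called fold enrichment here. That reading comes from the file format and the values, since the sources do not name the quantity, and it serves to describe and rank peaks within a list.

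The mark lay at the transcription start sites (TSS) of most protein-coding genes. A replicated peak lay within 1000 bp of the 5′ end of 13337 of 21911 protein-coding genes, which is 60.9% (exact binomial 95% interval 60.2 to 61.5, counting error only). Replicate 1 marked 13584 genes and replicate 2 marked 13346, a mean share of 61.5% ± 0.768 (SD, n = 2), and 13096 genes had a peak in both. Among genes in the top 5% of both replicates, the highest fold enrichment in the replicated list was at Sp3, a zinc finger transcription factor, with 55.6. Next came Dbn1, which encodes the actin-binding protein drebrin of neurons, with 55.5, Mex3b with 54.8 and Tnrc18 with 54.8. Marcksl1 and Marcks, substrates of protein kinase C that bind actin, had 53.9 and 51.0. Actb, the cytoplasmic beta-actin, had 53.1, the splicing factor gene Srsf6 had 52.6, Bahcc1 had 51.8, and Sox11, a transcription factor of immature neurons, had 50.02. The median over all genes with a replicated peak was 16.3. Across the genes with a peak in both replicates, which are not independent replicates, Spearman's rho of the fold enrichment was 0.897.

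The genes that pattern the forebrain and mark its main lineages nearly all carried the mark. All 16 forebrain patterning transcription factors had a replicated peak at the TSS, against 60.8% of other protein-coding genes, and all 16 had a peak in each replicate. The strongest were Nr2f1, a nuclear receptor that patterns cortical areas (chromosome 13, TSS at 78199757), with a fold enrichment of 47.2, Foxg1, which specifies the telencephalon (chromosome 12, TSS at 49382660), with 44.3, Meis2 with 33.2, and Lhx2, a selector gene of the cortex, with 31.0. All 16 genes of the cortical excitatory lineage were also marked, in the replicated list and in each replicate. Bcl11b, a transcription factor of deep-layer projection neurons, had 39.3, Cux1, an upper-layer factor, had 27.1, Tle4 had 26.6 and Neurod2 had 22.0. These are the 4 strongest of the list, whose median of 12.4 lay below the 16.3 of all marked genes, at the 8.09 percentile of random lists. Of the 16 genes of radial glia and neural progenitors, 15 were marked in the replicated list and 14 in each replicate. They included Id4 with 35.6, Sox2 with 35.1, Sox1 with 32.9, and the Notch target Hes5 with 26.3. Of the 16 genes of the ventral telencephalon and GABAergic lineage, 15 were marked in the replicated list and in each replicate. Gad2, an enzyme of GABA synthesis, had 20.98, Dlx1 had 20.9, Ascl1 had 20.8 and Dlx5 had 20.5, while the median of the list was 15.1. These 4 lists were marked more often than other genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 25 lists, adjusted exact p = 0.00125 for the patterning factors and the cortical list and 0.0142 for the other pair). Among promoters of like CpG content only the cortical call held, with adjusted exact p of 0.407 for patterning factors, 0.476 for radial glia and 1 for GABAergic genes. With all 16 patterning factors marked, no higher count was possible, so the matched test could not have passed above other genes. It does not decide the question for that list. Radial glia and GABAergic genes, with 15 of 16 marked in each list, left room for only 1 more, so it decides little for them too. For radial glia the call also ended with the peaks of either replicate alone, with an adjusted exact p of 0.0587 in replicate 2 and 0.0651 in replicate 1.

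**Figure D1:**
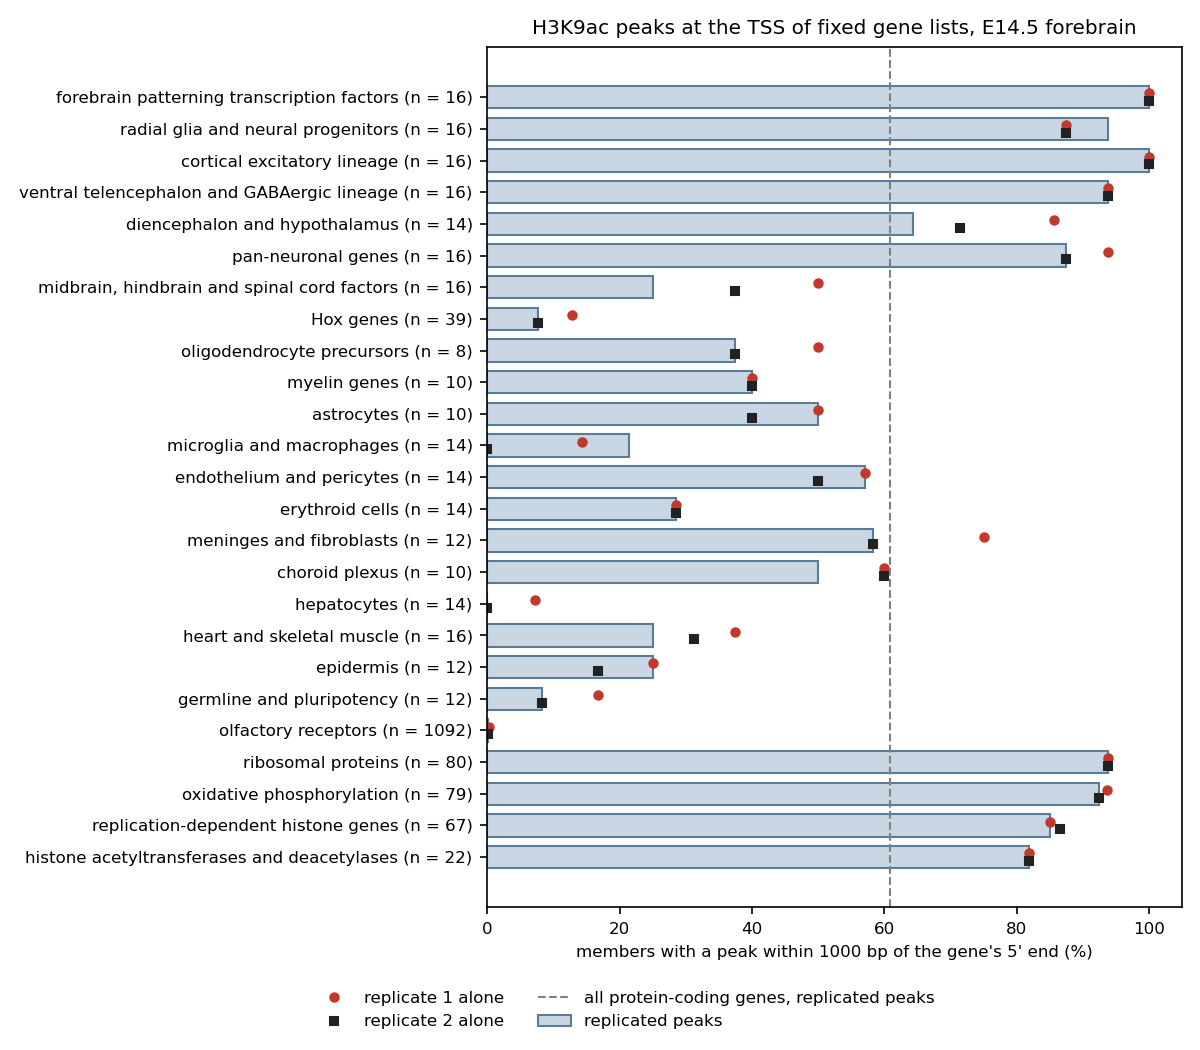
Share of the members of each of 25 gene lists with an H3K9ac peak within 1000 bp of the gene's 5′ end, in percent. Bars show the replicated peaks, circles replicate 1 alone, squares replicate 2 alone, and the dashed line the share of all protein-coding genes, 60.9%. Forebrain patterning factors and the cortical lineage stand at 100%, Hox genes at 7.69% and hepatocyte genes at 0.

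Of the pan-neuronal genes, 14 of 16 had a replicated peak (adjusted exact p = 0.0552, Fisher's exact test), which did not pass the threshold. The call depended on the setting. With replicate 1 alone 15 of 16 were marked (adjusted exact p = 0.0169). The list also passed with a −log10 q of at least 5 (0.0305) and a fold enrichment of at least 4 (0.0292). It passed with windows of 500 and 2500 bp (0.0335 and 0.01615) and all transcript 5′ ends (0.0022). It did not pass with replicate 2 alone (0.0587), with the pooled peaks (0.0678) or among promoters of like CpG content (0.187). The microtubule regulator Stmn1 had a fold enrichment of 41.1, the neuronal tubulin Tubb3 had 33.8, the RNA-binding protein gene Elavl3 had 30.2 and Map2 had 20.7. In the first 6 lists, which cover the forebrain lineages, 4 members outside the diencephalon list lacked a replicated peak at the gene's 5′ end, namely Notch1, Gad1, L1cam and Rbfox3. Each of the 4 had a replicated peak at the 5′ end of another annotated transcript, a check made after the values were seen, with a fold enrichment of 21.9 for Notch1, 16.7 for Gad1, 12.2 for L1cam and 21.7 for Rbfox3.

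Regional genes of the diencephalon and hypothalamus were marked no more often than other genes, and with a lower fold enrichment. Of 14 members, 9 had a replicated peak (64.3%, adjusted exact p = 1, Fisher's exact test), with 12 in replicate 1 and 10 in replicate 2. Tcf7l2, a factor of the thalamus, had a fold enrichment of 20.2, Vax1 had 18.3, Lhx9 had 8.23 and Lhx1 had 6.93. Foxb1, Nkx2-2, Otp and Rax were among the members without a replicated peak at the 5′ end. At another transcript's 5′ end, Nkx2-2 had a peak of 3.69 and Otp 4.05, while Foxb1 and Rax had none. The median of the 9 marked genes was 6.93, at the 0.31 percentile of 10000 random lists of as many marked genes, but ranked by peak width the list lay at the 79.195 percentile.

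Regulators of other body regions were marked less often than other genes. Only 3 of 39 Hox genes, which pattern the hindbrain, spinal cord and trunk, had a replicated peak (7.69%, adjusted exact p = 5.59e-11, Fisher's exact test), with 5 in replicate 1 and 3 in replicate 2. These were Hoxa7 with a fold enrichment of 4.69, Hoxa1 with 3.73 and Hoxd1 with 3.63. Hox genes lie close together in clusters, and the test counts them as independent. Of the 16 factors of the midbrain, hindbrain and spinal cord, 4 had a replicated peak (adjusted exact p = 0.00895). Mafb, which is also a factor of macrophages, had 16.9, En1 had 5.81, Atoh1 had 4.85 and Ptf1a had 4.37. That call depended on the peak set, since 8 members had a peak in replicate 1 and 6 in replicate 2, with adjusted exact p of 0.397 and 0.0994. It also ended with the 2500 bp window (0.111) and with all transcript 5′ ends (0.167). With the pooled peaks the list stood 6.12 percentage points above other genes (adjusted exact p = 0.906).

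Genes of other tissues were mostly unmarked. None of the 14 hepatocyte genes had a replicated peak (adjusted exact p = 9.81e-06, Fisher's exact test), and 1 had a peak in replicate 1. Germline and pluripotency genes were marked in 1 of 12 cases (adjusted exact p = 0.000902), the RNA-binding protein gene Dazl with a fold enrichment of 8.69. Heart and skeletal muscle genes were marked in 4 of 16 (adjusted exact p = 0.00895), with Ckm, the muscle creatine kinase, at 6.58, Des at 3.71, Myod1 at 3.66 and Myh7 at 2.70. With the peaks of replicate 1 alone, 6 of 16 muscle genes were marked and the adjusted exact p was 0.106. Epidermal genes were marked in 3 of 12 (adjusted exact p = 0.0259), with Lor at 11.3, Perp at 10.6 and Grhl3 at 3.85. The muscle and epidermis calls also ended with the 2500 bp window (adjusted exact p = 0.408 and 0.214) and with all transcript 5′ ends (0.0527 and 0.18), and the muscle call with the pooled peaks (0.104). Among promoters of like CpG content the hepatocyte, muscle and epidermis calls all ended (adjusted exact p = 0.0636, 0.233 and 0.373, exact conditional test). None of the 14 hepatocyte genes was marked, so no lower count was possible and the matched test could not have passed below other genes. It does not decide for that list. The Lor window had no peak in either replicate alone. Of 1092 olfactory receptor genes, 1 had a replicated peak, Olfr658 with 3.89. Its p-value lay below the smallest number the software can represent.

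Cell types that are rare in the forebrain at this age, or mature later, gave mostly low peaks. Microglia and macrophage genes were marked in 3 of 14 (adjusted exact p = 0.00895, Fisher's exact test), P2ry12 with 3.82, Cx3cr1 with 3.51 and C1qb with 2.61, and replicate 2 alone had a peak at none of them. Erythroid genes were marked in 4 of 14 (adjusted exact p = 0.038). Among promoters of like CpG content both calls ended, at -2.60 points for microglia and 5.19 points for erythroid genes. The erythroid transcription factor gene Klf1 had 12.5, Gypa had 7.44, Epor had 5.97 and Tal1 had 3.58. The alpha- and beta-globin genes had none. They include near-identical copies, and between 19.4% and 64.0% of the 32-base words in the windows of Hba-a1, Hba-a2, Hbb-bt and Hbb-bs occur once in the genome, so the state of these 4 is uncertain. The windows of Hbb-bh1, Hbb-y and Hba-x are at least 96.4% unique and had no peak either. The other lists of this kind did not differ from other genes in the share marked. Oligodendrocyte precursor genes had 3 of 8 marked (adjusted exact p = 0.345, and 0.0156 with a −log10 q of at least 5), Olig2 with 8.53, Pdgfra with 3.35 and Olig1 with 3.07. Myelin genes had 4 of 10 (adjusted exact p = 0.268), with Mbp at 17.3, Cnp at 10.4, Myrf at 7.57 and Cldn11 at 5.01. Astrocyte genes had 5 of 10 (adjusted exact p = 0.599), with the glutamate transporter gene Slc1a2 at 16.7 and the gap junction gene Gja1 at 14.3. Endothelial and pericyte genes had 8 of 14 (adjusted exact p = 0.858), with the VEGF receptor gene Kdr at 9.01, Kcnj8 at 6.93 and Erg at 6.61. Genes of meninges and fibroblasts had 7 of 12 (adjusted exact p = 1), with Fn1 at 12.3, Twist1 at 6.77 and Foxc1 at 6.34. Choroid plexus genes had 5 of 10 (adjusted exact p = 0.599), with Foxj1 at 9.81, Kl at 7.73 and Otx2 at 7.09.

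Most ribosomal protein and oxidative phosphorylation genes were marked. Ribosomal protein genes had a replicated peak in 75 of 80 cases (adjusted exact p = 2.52e-10, Fisher's exact test), with Rps19 at 42.2, Rpl13a at 40.7, Rpl32 at 36.1 and Rps6 at 35.9. Genes of oxidative phosphorylation were marked in 73 of 79 (adjusted exact p = 2.09e-09), with Atp5g3 at 34.5 and Atp5b at 31.7. Among promoters of like CpG content both calls ended, at 2.04 points above other genes (adjusted exact p = 0.805) and 6.03 points (0.141). Replication-dependent histone genes, which are mostly expressed in dividing cells, were marked in 57 of 67 (adjusted exact p = 9.95e-05), but their difference turned from 24.3 to -10.5 points among promoters of like CpG content. They were led by Hist3h2a at 27.3 and Hist3h2ba at 25.7. The enzymes that add and remove histone acetyl groups were marked in 18 of 22 (adjusted exact p = 0.0684, and 0.000502 with all transcript 5′ ends), with the acetyltransferase gene Ep300 at 42.0 and the deacetylase gene Hdac2 at 31.9.

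Many of these differences in share became smaller among promoters of like CpG content. Genes were compared within quintiles of the CpG ratio of the TSS window. Of the 7 lists that had passed above other genes, only the cortical excitatory list still did so. It stood 20.2 percentage points above other genes (adjusted exact p = 0.0286, exact conditional test). The patterning factors then stood 9.12 points above other genes (adjusted exact p = 0.407). All of them were marked, so the matched test had no higher count with which to pass and does not decide for that list. Radial glia and GABAergic genes were 7.44 and 1.21 points above, also short of the threshold. Each list had 15 of 16 members marked, so only 1 more was possible and the matched test decides little for them. Hox genes stood 79.3 points below other genes of like CpG ratio (a difference of -79.3, adjusted exact p = 7.29e-39), and the midbrain, hindbrain and spinal cord factors also stood below (-65.96, adjusted exact p = 2.07e-13). Hox, histone and olfactory receptor genes include close neighbours that the test counts as independent, so their p-values may be too small. Germline genes stood at -55.8 points. Olfactory receptor genes still passed, but their difference shrank from -63.97 to -4.95 points. The calls of the microglia, erythroid, hepatocyte, muscle and epidermis lists ended. For hepatocyte genes, none of which was marked, the matched test had no lower count with which to pass and does not decide. Diencephalon genes fell to a difference of -31.0 points (adjusted exact p = 0.000633), and histone genes now passed below other genes (adjusted exact p = 0.000553).

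Peak strength separated the lists further, with 2 lists in the top 2.5% of random lists and 12 in the bottom 2.5%. Among marked genes, the median fold enrichment of ribosomal protein genes was 24.4, above all 10000 random lists in the replicated list and in each replicate. The patterning factors had a median of 24.3, at the 99.89 percentile, with the 98.26 percentile in replicate 1 and the 90.23 percentile in replicate 2. Histone genes had a median of 10.6, at the 0.01 percentile, and stayed at or under the 0.115 percentile in each replicate. Marked genes of the endothelium, with a median of 5.57, and of the meninges, with 5.97, lay at the 0.02 and 0.2 percentile. Peak width gave another order. By width the cortical list rose to the 99.165 percentile and the GABAergic list to 100, meninges genes to 9.285, and ribosomal protein genes fell to 93.645.

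**Figure D2:**
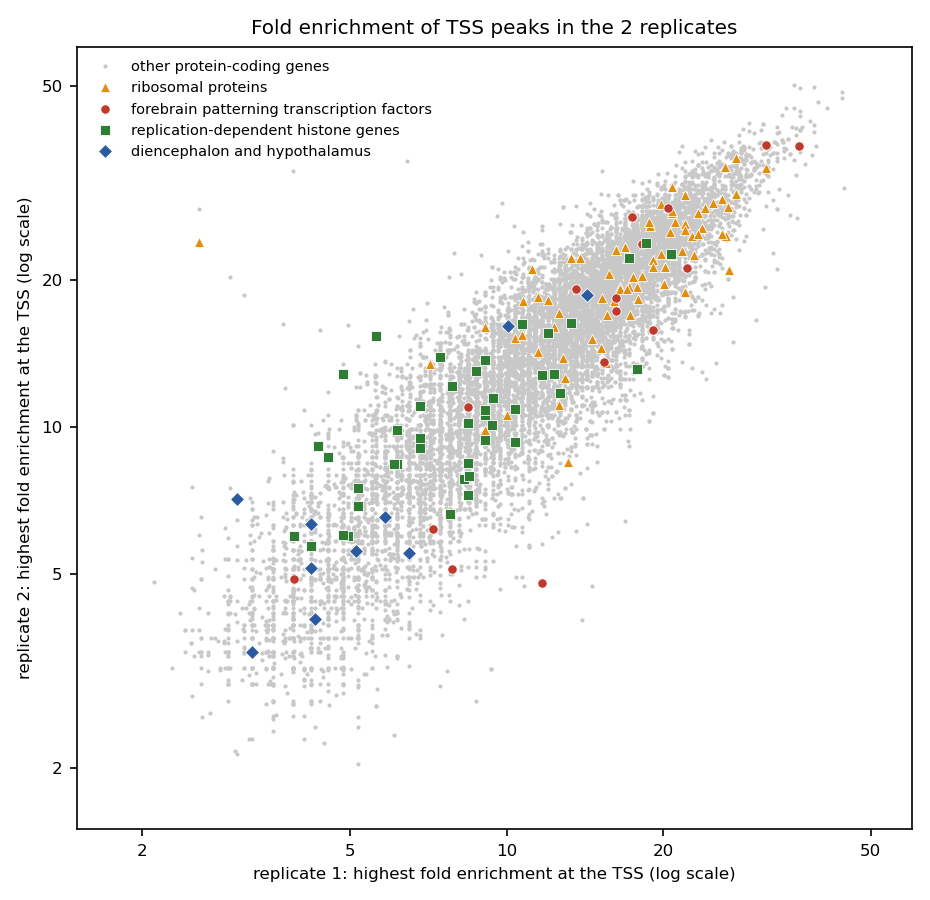
Highest fold enrichment of a peak within 1000 bp of the gene's 5′ end in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), with 1 point per protein-coding gene marked in both. Ribosomal protein genes and most patterning factors lie towards the upper right, while histone genes and most diencephalon genes lie lower. Spearman's rho across the 13096 genes was 0.897.

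Most of the replicated peaks lay at a TSS. The share within 1000 bp of the 5′ end of any annotated transcript was 57.2% in the replicated list, with 5.50% in exons, 22.6% in introns and 14.7% between genes. It was 40.7% in replicate 1 and 53.3% in replicate 2, a mean of 47.0% ± 8.94 (SD, n = 2). In both replicates the peaks at a TSS were stronger and wider than distal ones. The median fold enrichment was 5.84 at the TSS and 3.24 elsewhere in replicate 1, and 8.68 and 3.61 in replicate 2. The median width was 626 bp and 226 bp in replicate 1, and 835 bp and 263 bp in replicate 2.

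Of the 15 widest marked regions, 8 lay over the TSS of a member of the 6 forebrain lists and 7 over the TSS of no member of any list. Joining replicated peaks at most 1000 bp apart gave 26194 domains, with a median width of 1127 bp, of which 613 spanned at least 5000 bp. The widest covered 42109 bp at Nr2f1 (chromosome 13, 78169774 to 78211882), and held 16 separate peaks, while the widest domain of replicate 1 there covered 18866 bp and that of replicate 2 37729 bp. Among the 15 widest were domains over the TSS of Pou3f3, a POU factor of neural cells (32057 bp), Foxg1 together with Gm43517 (30349 bp, chromosome 12, 49372978 to 49403326), Dlx5 and Dlx6 (29790 bp, with 32259 bp in replicate 1 and 18533 bp in replicate 2), Nr2f2 (29358 bp), Bcl11a with A830031A19Rik (27820 bp), Lhx2 (25085 bp), Meis2 (24303 bp), Pax6 (24074 bp), and Dlx1 and Dlx2 (22884 bp). Domains of 27201 bp and 26243 bp overlapped the genes Nfix and Nfib, away from the 5′ end of the gene record. Whether they cover the 5′ end of another annotated transcript was not checked. The remaining 3 of the 15 covered no protein-coding TSS, and each held a gene of the microRNA miR-9, a neural microRNA. These 3 genes were named after their values were seen. They were Mir9-1 in 34539 bp on chromosome 3 (88197659 to 88232197), Mir9-3 in 32674 bp on chromosome 7 (79496032 to 79528705), and Mir9-2 in 30153 bp on chromosome 13 (83712731 to 83742883), where a long non-coding RNA gene, C130071C03Rik, also starts. Of the 15 domains, 14 were again among the 15 widest in replicate 2 and 13 in replicate 1.

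**Figure D3:**
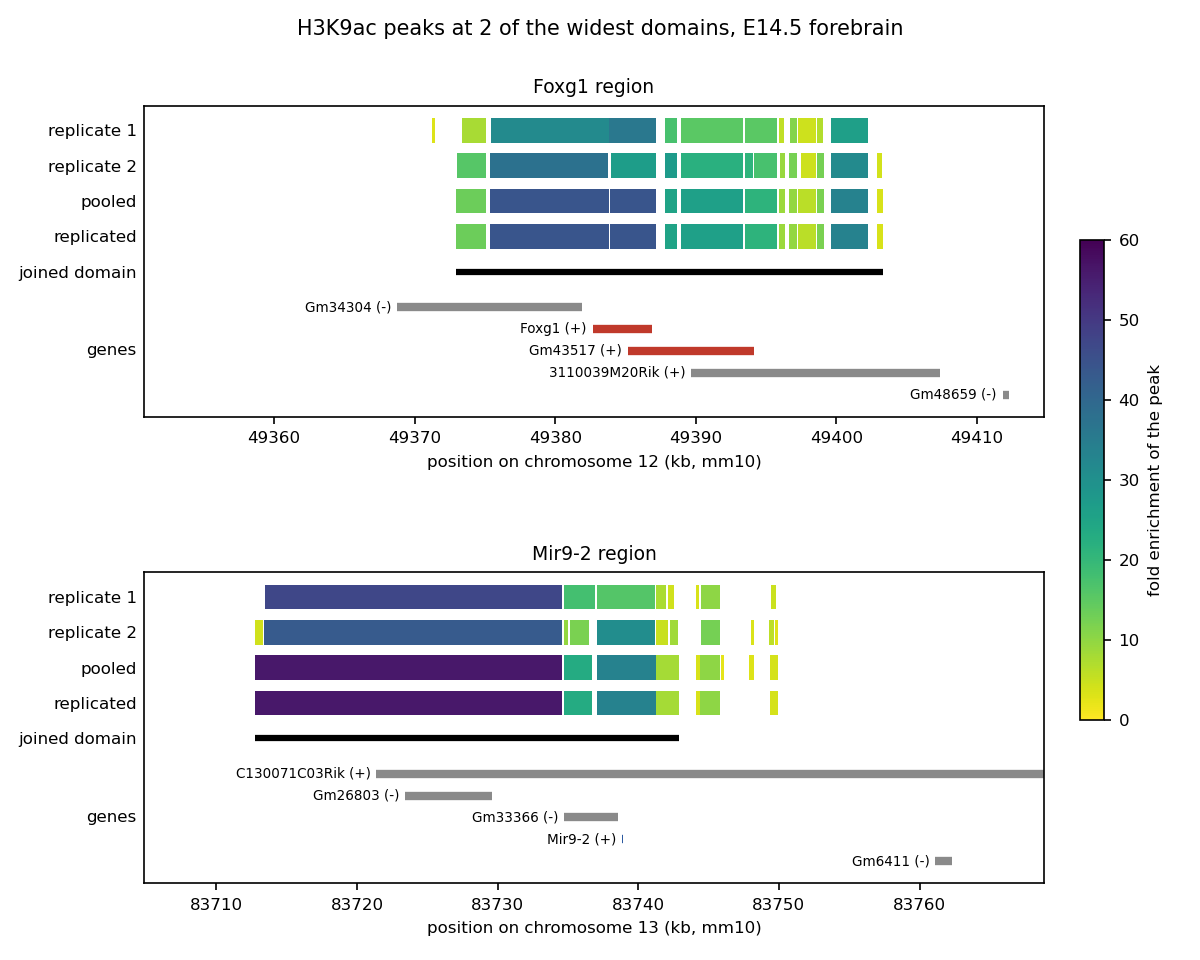
Peaks of the 4 lists around Foxg1 (top) and Mir9-2 (bottom) by position in kb on mm10, coloured by the fold enrichment of each peak. The black bar is the joined domain, 30349 bp at Foxg1 and 30153 bp at Mir9-2. Red bars are protein-coding genes, blue the microRNA gene and grey other genes, with the strand in brackets.

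Genes of the forebrain lists had many distal peaks, the pan-neuronal list less clearly. Of 14978 replicated peaks farther than 1000 bp from any TSS, 12075 had their nearest protein-coding TSS within 100000 bp, a mean of 0.551 per gene. The nearest gene is only a label here. Patterning factors had a mean of 5.25 such peaks, cortical lineage genes 4.88, radial glia genes 4.38 and GABAergic genes 3.63, each above all 10000 random lists of the same size. Diencephalon genes had 2.64, at the 99.885 percentile, and pan-neuronal genes 1.44, at the 97.38 percentile (between 85.855 and 98.53 over the alternatives). Factors of the midbrain, hindbrain and spinal cord, few of which were marked at the TSS, had 1.56, at the 98.335 percentile, and 0.875, at the 91.765 percentile, when only peaks within 50000 bp counted. Random lists were not matched on the distance between neighbouring genes, which sets how many peaks a gene can receive. Bcl11b and Gins2, a replication protein gene that neighbours Gse1, had the most, with 30 each, and Gse1 itself had 29. The corepressor gene Ncor2 had 27, Tcf20 had 23, G430095P16Rik had 22, and Irf2bpl and Prdm16, a regulator of neural stem cells, had 20 each. Cstad, Flrt1 and Trak1 had 19 each, Ephb2 and Notch2 18 each, Zmiz1 17 and Kif26a 16. Of these 15 genes, only Bcl11b belonged to any of the 25 lists. Distal counts moved with the peak set, with 32963 assigned peaks in replicate 1 and 16912 in replicate 2.

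The replicates shared their strong peaks and differed in weak ones. Counting an overlap of at least 50% of the smaller peak, 31196 replicate 1 peaks (45.9%) were shared with replicate 2, and 29259 replicate 2 peaks (66.02%) with replicate 1. Shuffling replicate 2 within chromosomes 100 times gave means of 1.71% and 2.42%, and at most 1.85% and 2.62%. Shared peaks had a median fold enrichment of 5.76 in replicate 1 and 7.11 in replicate 2, against 3.21 and 3.39 for the others. Over 22760 peaks that overlapped 1 to 1, Spearman's rho was 0.884, between 0.828 on chromosome X and 0.912 on chromosome 16. Among peaks with a −log10 q of at least 5, the shared portions were 90.04% and 84.7%.

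The replicated list held 57.9% of the pooled peaks (exact binomial 95% interval 57.5 to 58.3), and each of its 35043 rows was identical to a pooled row. Peaks of replicate 1 were represented in it at 56.9% (56.5 to 57.3) and those of replicate 2 at 81.9% (81.5 to 82.2). Of the replicated peaks, 77.2% were overlapped by a peak of both replicates under the same rule.

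Few genes were marked in a single replicate. A TSS peak was present in replicate 1 only at 488 genes and in replicate 2 only at 250. With equal numbers of top peaks the counts were 265 and 394. Too few list members fell in these sets to show whether a list went with a replicate. Of the 25 lists, 9 had no member in either set and none had more than 6, and the lowest unadjusted p of Fisher's exact test was 0.339, with adjusted exact p of 1 throughout. The strongest genes marked in replicate 1 only were Ube2v2 (fold enrichment 21.1), Zkscan7 (14.3), Sdhaf1 (13.6), Snrpa1 (9.08) and Trpv2 (8.61). Those of replicate 2 only were Rp9 (18.4), Gpr149 (10.8), A930004D18Rik (10.3), Hrc (10.2) and Syndig1 (9.03). At all 10 the other replicate had a peak just outside the window, between 1003 and 1295 bp from the TSS. That distance was checked after the names were seen.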

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

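A few peaks lay on contigs that no comparison used. Replicate 1 had 10 peaks outside the main chromosomes and replicate 2 had 9, and the pooled and replicated lists had 9 each, all above the 3 that a count of 0 would allow. The highest fold enrichment there was 14.6, on a contig assigned to chromosome 4 without a position, in the pooled and replicated lists.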

How the results depend on the processing

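The set of alternatives was fixed before the data were examined, except the test of lists in wide domains. The bounds of the top and bottom 2.5% of random lists were also chosen after the data were seen. The shares of peaks moved with almost every rule, while between 10 and 14 of the 15 widest domains were found again under every alternative. With a −log10 q of at least 5, 90.04% of replicate 1 and 84.7% of replicate 2 peaks were shared, 98.2% of pooled, 98.4% of replicate 1 and 99.2% of replicate 2 peaks were in the replicated list, 69.9% of replicated peaks lay at a TSS, 59.4% of genes were marked, 210 and 416 genes were marked in replicate 1 or 2 only, 6296 distal peaks were assigned and 9 of the 15 genes with most distal peaks were found again. With a fold enrichment of at least 4, the shared portions were 82.5% and 78.7%, the TSS share 73.9% and the share of genes 58.8%. Fewer weak peaks enter by construction in both. With equal numbers of top peaks, the shared portions were 63.1% and 60.6%, and 265 and 394 genes were marked in 1 replicate only. An overlap of 1 bp gave shared portions of 49.7% and 71.1%, and 57.4% and 82.2% of replicate 1 and 2 peaks in the replicated list. Requiring 50% of both peaks gave 34.4% and 52.7%, a rho of 0.920, and 36.3% and 58.9% in the replicated list. With the pooled peaks 40.9% lay at a TSS, 62.6% of genes were marked and 28693 distal peaks were assigned. Windows of 500 and 2500 bp marked 59.8% and 62.6% of genes, and the larger gave a TSS share of 66.3%. All transcript 5′ ends marked 64.6%. Leaving out each replicate gave TSS shares of 40.7% to 53.3%, 60.9% to 61.996% of genes marked, 16912 to 32963 distal peaks assigned, and 1 to 3 lists in the top 2.5% of random lists by strength, against 2. Ranked by width, 5 lists in place of 2 lay in the top 2.5% and 7 in place of 12 in the bottom 2.5%. Without joining, 196 domains reached 5000 bp and 2 lists in place of 6, patterning factors and GABAergic genes, were more often in wide domains, and a gap of 3000 bp gave 1327. Reaching only 50000 bp, 8 of the 15 genes with most distal peaks were found again. Matched on the CpG ratio, 1 list in place of 7 was marked more often. In the test of the share marked at the TSS, over its alternatives and lists, a call ended 21 times and a list newly passed 9 times with no change of direction. Differences in share from other genes changed sign with matching on the CpG ratio for diencephalon (-31.0 points), astrocytes (13.8), erythroid cells (5.19), meninges (3.29) and histone genes (-10.5). They did so with the pooled peaks for midbrain, hindbrain and spinal cord factors (6.12), endothelium (8.80) and meninges (4.03), and with all transcript 5′ ends for meninges (10.4) and choroid plexus (5.40). Meninges also changed sign with the 2500 bp window (4.04), and ranged from -2.58 to 13.01 points with either replicate left out. Beyond the settings whose construction explains the shift, the cause was not tested. No paired analysis was possible because there is 1 group. Depth is unknown, so a missing weak peak does not show an unmarked region.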

Other observations

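The test of lists in wide domains was chosen after the peaks were seen, the test of joining in 3 of these lists after their values were seen, and the intervals of the chromosome X tests on top peaks and on fold enrichment were added after their first result. Members of 5 of the 6 forebrain lists lay in wide domains of at least 5000 bp more often than other marked genes. Among marked genes, 14 of 16 patterning factors lay in such a domain (87.5%, against 4.01% of other marked genes, adjusted exact p = 9.25e-17, Fisher's exact test). The same held for 10 of 15 GABAergic genes (adjusted exact p = 3.95e-10), 8 of 16 cortical genes (3.71e-07), 8 of 15 radial glia genes (2.41e-07) and 7 of 9 diencephalon genes (5.32e-08). Dlx5 and Dlx6 shared 1 domain and Dlx1 and Dlx2 another, although the test counts genes as independent. Examples picked after their values were seen are Sox1 in 21092 bp, Sox2 in 20787 bp, Tbr1 in 13500 bp, the vesicular glutamate transporter gene Slc17a6 in 13021 bp, Sp9 in 11888 bp and Lhx9 in 12464 bp. Pan-neuronal genes had 3 of 14 (adjusted exact p = 0.0639), ribosomal protein genes 3 of 75 and oxidative phosphorylation genes 1 of 73. Pan-neuronal genes passed without replicate 1 (adjusted exact p = 0.0327) and with a −log10 q of at least 5 (0.033), and with gaps of up to 3000 bp joined ribosomal protein genes passed with 15 of 75 (0.0186). Histone genes had 9 of 57 (adjusted exact p = 0.00201), 8 of them in 2 clusters of neighbouring genes on chromosome 13. Without replicate 2 the histone call ended and diencephalon genes had 3 of 12 (adjusted exact p = 0.0461). Without joining of peaks, only patterning factors, with 10 of 16, and GABAergic genes, with 4 of 15, passed, while radial glia, cortical and diencephalon genes had 1 each (0.66).

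Protein-coding 5′ ends were taken from the gene record, and those of other annotated transcripts were not checked. Of the 613 wide domains, 148 covered no such 5′ end. Of these, 104 overlapped the body of a protein-coding gene, 43 held the 5′ end of a long non-coding RNA gene and 15 that of a microRNA gene. The Mir9-2 domain, where the highest peak had a fold enrichment of 56.1, was one of them.

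The link between forebrain genes and wide domains was weighed against 3 technical explanations. In the 6 forebrain lists together, 50 of 85 marked genes lay in a wide domain against 498 of 13252 others. The odds ratio was 36.5 (95% interval 23.0 to 58.6, genes taken as independent though some share a domain). Within quintiles of the CpG ratio the lower bound of the odds ratio was 23.2, and within quintiles of fold enrichment it was 29.1. Neither the CpG ratio of the TSS window nor the calling of stronger peaks as wider therefore accounts for it alone. The CpG ratio covers only 1000 bp on either side of the 5′ end, so CpG content farther along a domain stays open. With single peaks of at least 5000 bp and no joining, 18 of the 85 and 125 others remained and the lower bound was 15.3, which argues against joining as the whole cause, but radial glia, cortical and diencephalon genes fell from 23 to 3 of 40 with a lower bound of 1.66, so joining stays open for them. No biological explanation was tested because there is 1 group.

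Replicate 1 had 1.05 times as many peaks as replicate 2 on chromosome X, against 1.41 to 1.62 times on the 19 autosomes. Among equal numbers of top peaks the X ratio was 0.829 (95% interval 0.756 to 0.907, peaks taken as independent), below the lowest autosome at 0.912. That argues against the larger number of replicate 1 calls as the whole cause. The 44316 top peaks are the whole replicate 2 list, weak calls included, so weak calls as a cause stay open. Autosomal peaks reweighted to the GC content of X peaks gave 1.55, which argues against GC content. The median log2 ratio of fold enrichment over 611 X peaks was -0.28 (-0.31 to -0.23), below every autosome (-0.21 to -0.18), with Xist at -0.42 and a median of -0.06 over only 3 Y peaks. A larger share of male embryos in the pool of replicate 1 may be a source of the difference. The labels give no numbers of each sex, and Xist is a single peak with no spread to judge it by.

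Replication-dependent histone genes were marked more often than other genes, though not among promoters of like CpG content. The median fold enrichment of the marked members was low, and 10 members had no peak. Reads shared between near-identical copies may account for some of the members without a peak. Whether they account for the low median could not be decided. The 10 unmarked members had a median of 4.24% unique 32-base words in the TSS window, against 76.5% in the 57 marked members (means 38.6% and 74.3%, one-sided permutation test of the means, p = 0.0003). The lowest values, 0 to 4.26%, were those of neighbouring genes from Hist1h2bq to Hist1h2br, named after their values were seen. The test counts these neighbours as independent, so its p-value is too small if they form 1 repeated block. Low shares among the unmarked members were limited to these neighbours. The mean of 38.6% requires that each of the other unmarked members lay above the 76.5% median of marked members. Shared copies explain those others poorly, and 2 of them were at least 90% unique. Among the 9 marked members with windows at least 90% unique, the median fold enrichment was 14.5, at the 30.94 percentile of random lists, against 10.6 for all 57. Medians of only 9 genes vary widely among random lists, so this value cannot decide the cause of the low median. The explanation stays open because the authors' handling of reads with several matches is not given in the sources used here. No biological explanation was tested.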
